A study of Homo sapiens with 6 samples.

How the data were processed

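RNA from 6 cultures of Cal27 cells, 3 controls and 3 with nanosheets, was sequenced as 150-base read pairs after poly(A) selection and a dUTP second strand, per the labels' protocols. The labels name the sequencer in 2 conflicting ways. The deposited table holds 29944 genes, each with a count and an FPKM value per sample, per the file headers, together with coordinates, gene names and GO and KEGG terms. The submitters' processing notes name cutadapt 1.9 and build hg38. The aligner, the counting program, the annotation release and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes may share reads.

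The deposited counts are whole numbers with a different total in each library, from 55192660 to 59868533. The deposited FPKM values, which the authors scaled by gene length and library depth, differ from the counts by 1 factor per gene and 1 per library. Low counts peak at 4 and 8: the value 4 was 3.18 to 4.07 times as frequent as the mean of 3 and 5 in each library. A read pair thus seems to have contributed about 4 counts, and a fold against controls at 0 was computed against a floor of 12 counts per library, or 3 read pairs. This floor was set after the data were seen and covers counting error only. In 6 genes, 1 library was at 0 while both others of its group exceeded 500 counts.

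Groups were taken from the treatment label. The main test was edgeR 4.0.16 (quasi-likelihood, filterByExpr, TMM scaling) in R 4.3.3, 2-sided, with Benjamini-Hochberg adjustment over 18325 genes and a threshold of 0.05. The plan provided for it if the table held counts, in place of limma 3.58.1 on log2(FPKM + 1), which became an alternative. CPM values are TMM-scaled, and log2 fold changes are given with their SE. The common dispersion was 0.124. Of the gene identifiers, 29154 matched GENCODE release 29, which gave transcript lengths, exon counts and gene classes, and coordinates are those of the table. On simulated counts (17463 genes, 200 drawn to change) edgeR recovered 33.3% of 2-fold and 75.3% of 4-fold changes. It made 12 false calls there, 10.53% of its calls. DESeq2 recovered 58.3% and 83.9% with 33.33% of its calls false. Limma was run there on CPM without length scaling (13937 genes). It recovered 48.8% and 84.5% with 8.33% false, rates that need not hold for limma on FPKM. The simulation changed far fewer genes than the 4209 called in the data, and the adjustment depends on that share. These rates of recovery and of false calls therefore need not hold for the data.

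Gene lists (34) were fixed before the data were examined, and 31 with at least 5 tested members were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Of 17 lists called, 5 hold with an estimated correlation: heat shock, immediate early genes, metallothioneins, endoplasmic reticulum chaperones and ribosome biogenesis. That setting raised p also where the estimate lay under the preset. The DNA replication list, with an estimate of 0.003, went from a camera p of 4.04e-05 to 0.0114. A call lost there thus does not by itself show correlated members. Genes named in the text by rule are 26 fixed beforehand, the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap, with a symbol and a mean of at least 5 FPKM, and up to 4 called members of each list with the smallest adjusted p. Outside this rule, MT1M, CD68, CSF1R, MT-ATP8, MTATP6P1, MT-RNR1, MT-RNR2, RN7SK, RMRP, FTH1, SLC7A11 and CHAC1 were named after their values were seen. Alternatives were DESeq2 1.42.0, no filter on counts, the replicate number as a block, each library left out, limma on FPKM with other pseudocounts (0.1, 0.01 and 5), filters, scalings, weights and moderation, stricter thresholds, an estimated correlation and fry. Added after the data were seen were counts divided by 4, RLE and upper-quartile scaling, library totals alone, totals without mitochondrial genes, HSPA1A and HSPA1B, and a robust fit. Tests of the closing section used Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, with 95% bootstrap intervals over genes from 2000 resamples, or 500 for decile-matched differences. No sample or per-sample column was left out.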

Results

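Cal27 is an established human cell line grown from an oral squamous cell carcinoma of the tongue. Transcripts were measured by poly(A)-selected RNA sequencing in 3 control cultures and 3 cultures given nanosheets, a composite of zeolitic imidazolate framework-8 (ZIF-8, a porous solid built from zinc ions and imidazolate linkers) grown on graphene oxide. Each culture was sampled at 6 h. The purpose stated for the material is ion interference combined with photothermal therapy, and the labels mention no irradiation of these samples. A total of 6 libraries were therefore compared in 2 groups, and the question was which transcripts differ with the nanosheets. The libraries held between 55192660 and 59868533 counts each. The labels name 3 different experiments, and the p-values measure the spread between these 3 cultures per group. Another label of the same samples describes a bacterial co-culture of several days, which conflicts with the 6 h label, and the groups here rest on the treatment label alone.

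In the nanosheet cultures 23 of 24 heat shock genes, all 8 metallothioneins and the zinc exporter SLC30A1 rose. So did 18 of 23 immediate early genes and 17 of 26 oxidative stress genes. Of 13 mitochondrially encoded protein-coding genes 12 fell, as did 13 of 24 genes of ribosome production. With an estimated correlation the calls on the oxidative stress list (adjusted p = 0.123) and the mitochondrial list (adjusted p = 0.0823) were lost, and the other 4 list calls held (adjusted p from 0.0118 to 0.047). Of 18325 genes tested with edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p under 0.05), 4209 changed, 1929 of them higher and 2280 lower. With at least a 2-fold change, 875 were higher and 808 lower, and 258 had a fitted fold change of at least 10-fold upward. Scaling by library totals alone gave 1577 higher and 2849 lower, and limma on the FPKM values gave 1446 higher and 2731 lower, while upper-quartile scaling gave 2229 higher and 1998 lower, so the balance of directions depends on the scaling. Without control replicate 3 the count was 2786. The groups did not overlap for 7829 genes (42.7%), where chance gives 10% for 3 against 3. Pearson's r across genes was 0.9587 to 0.9644 within the controls, 0.9526 to 0.9548 within the nanosheet libraries and 0.9186 to 0.926 between groups, and genes are not independent replicates.

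The heat shock genes rose nearly throughout. Of the list, 23 of 24 measured members rose and none fell (23 also when adjusted over the list alone). Their median log2 fold change was 1.47 (camera, adjusted p = 2.86e-24, and adjusted p = 0.0118 with an estimated correlation). HSPA1A (ENSG00000204389, hg38 chromosome 6, 31815543 to 31817946) and HSPA1B (ENSG00000204388, chromosome 6, 31827738 to 31830254) encode the inducible HSP70 chaperone. HSPA1A went from 286.5 ± 26.4 to 10780 ± 354 CPM (counts scaled to library size, SD, n = 3 per group). The log2 fold change was 5.23 ± 0.08 (SE, edgeR adjusted p = 1.63e-07). HSPA1B went from 293.6 ± 12.1 to 10080 ± 244 CPM (SD, n = 3), by 5.10 ± 0.06. The 2 genes are near-identical, so the split of reads between them is uncertain. Together they held 0.060% ± 0.003 of the counts in controls and 2.02% ± 0.05 in nanosheet cultures (SD, n = 3). HSPA6 rose from 1.49 ± 0.61 to 1047 ± 70.1 CPM, and its near-identical pseudogene HSPA7 from 0.38 ± 0.32 to 118 ± 14.3 CPM, with an uncertain split between them. The co-chaperones DNAJB1 (log2 fold change 3.72 ± 0.14), DNAJB4 (3.62 ± 0.11) and BAG3 (3.00 ± 0.08) rose as well.

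**Figure D1:**
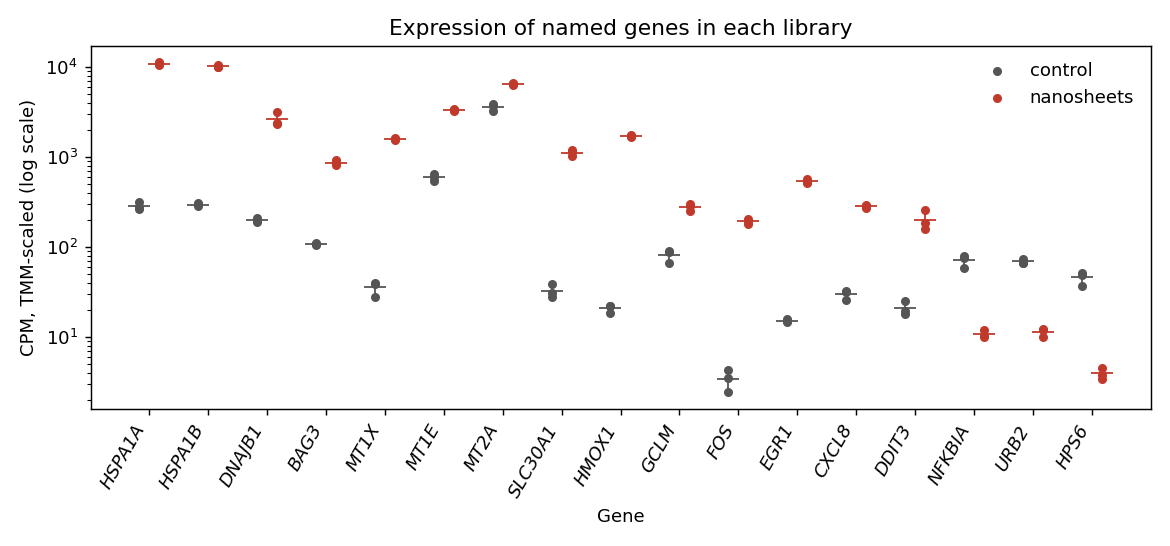
CPM of 17 named genes in each of the 6 libraries on a log axis, with points for libraries, dashes for group means and bars for the SD. HSPA1A lies at 286.5 CPM on average in controls and 10780 with nanosheets, and in each gene shown the 3 libraries of a group lie apart from those of the other group.

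All 8 measured metallothioneins, small proteins that bind zinc and other metals, rose (8 also when adjusted over the list alone, camera adjusted p = 4.81e-12, and adjusted p = 0.047 with an estimated correlation). Their median log2 fold change was 6.19 as fitted, and 4.83 with 3 members that were at 0 in every control set at a lower bound. MT1X (ENSG00000187193, chromosome 16, 56682470 to 56684196) went from 35.3 ± 6.4 to 1570 ± 52.6 CPM (log2 fold change 5.47 ± 0.15, edgeR adjusted p = 2.36e-06). MT2A, already abundant at 3592 ± 350 CPM, went to 6448 ± 174 CPM (0.84 ± 0.07), MT1E rose by 2.49 ± 0.08 and MT1F by 3.81 ± 0.16 on the log2 scale. MT1G and MT1B were at 0 in the 3 controls, and against a floor of 12 counts per library they were at least 86.6-fold and at least 211-fold higher. The MT1 genes are close copies of each other, so the share of each is uncertain.

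Among the zinc exporters of the SLC30 family, 2 of 7 measured members rose and 1 fell (2 and 1 also when adjusted over the list alone, camera adjusted p = 0.095). Without control replicate 3 that list was called (adjusted p = 0.038). SLC30A1 (ENSG00000170385, chromosome 1, 211571568 to 211579161), the zinc exporter of the plasma membrane, went from 32.2 ± 5.6 to 1104 ± 86.7 CPM (SD, n = 3, log2 fold change 5.10 ± 0.15, edgeR adjusted p = 2.55e-06). SLC30A2 was at 0 in controls and at least 5.56-fold higher, at 1.10 ± 0.16 CPM. SLC30A4 fell by 0.71 (adjusted p = 0.0331), a call lost without control replicate 3 (adjusted p = 0.12) and without each of the other 5 libraries (0.0571 to 0.098). None of 11 SLC39 zinc importers rose and 3 fell, SLC39A3, SLC39A13 and SLC39A9 (3 also when adjusted over the list alone). The list's median of 0.05 and mean of −0.17 differ in sign (camera, adjusted p = 0.854). Calls on these 3 are lost when some single libraries are left out (adjusted p from 0.0502 to 0.0945). SLC39A10 was at 41.8 ± 5.1 and 40.3 ± 17.3 CPM (edgeR, adjusted p = 0.927).

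The NRF2 list, antioxidant and detoxifying genes, had 17 of 26 members higher and none lower (17 also when adjusted over the list alone). Its median was 0.70 (camera, adjusted p = 2.26e-09, but adjusted p = 0.123 with an estimated correlation). HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35390293), which encodes heme oxygenase 1, went from 20.8 ± 2.3 to 1705 ± 59.9 CPM (log2 fold change 6.36 ± 0.11, edgeR adjusted p = 1.63e-07). GCLM, a subunit of the enzyme that starts glutathione synthesis, rose by 1.78 ± 0.14, TXNRD1 by 1.60 ± 0.21 and SRXN1 by 0.60 ± 0.07. Of 15 ferroptosis regulators, 9 rose and 1 fell (9 and 1 also when adjusted over the list alone, camera adjusted p = 2.79e-05, and adjusted p = 0.056 with an estimated correlation). HMOX1, FTL (0.80 ± 0.08) and SAT1 (0.82 ± 0.07) were among those that rose. HMOX1, FTL, FTH1 and SLC7A11 stand in the NRF2 list too, and all rose. CHAC1 and PTGS2, also higher, stand in the ATF4 and the NF-kB list.

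Of the endoplasmic reticulum chaperone list, 15 of 19 members rose and none fell (15 higher and 1 lower when adjusted over the list alone). Some members are not chaperones themselves, such as XBP1, a transcription factor, and HERPUD1. The median was 0.57 (camera, adjusted p = 9.43e-09, and adjusted p = 0.0464 with an estimated correlation). HSPA5, the main HSP70 of this compartment, went from 1228 ± 39.2 to 3892 ± 74.1 CPM (1.66 ± 0.05). DNAJB9 rose by 3.06 ± 0.18, HERPUD1 by 2.19 ± 0.15 and XBP1 by 1.69 ± 0.10. The ATF4 list was divided, with 7 of 26 members higher and 8 lower (8 and 9 when adjusted over the list alone). Its median of −0.03 and mean of 0.25 differ in sign (camera, adjusted p = 0.871). DDIT3, a stress-induced transcription factor, rose by 3.26 ± 0.22, ATF3 by 2.40 ± 0.14, PPP1R15A by 2.69 ± 0.07, SESN2 by 2.41 ± 0.12 and ATF4 itself by 0.55 ± 0.09. TRIB3 was at 67.5 ± 13.1 and 74.2 ± 5.2 CPM (edgeR, adjusted p = 0.572).

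Immediate early genes, transcribed within minutes of many stimuli, rose in 18 of 23 cases, with 1 lower (19 and 2 when adjusted over the list alone). Their median was 2.21 (camera, adjusted p = 4.82e-15, and adjusted p = 0.0129 with an estimated correlation). FOS went from 3.39 ± 0.96 to 192 ± 10.0 CPM (5.82 ± 0.23, edgeR adjusted p = 6.25e-06) and EGR1 from 15.2 ± 0.6 to 535.6 ± 25.1 CPM (5.14 ± 0.09). DUSP1 rose by 4.64 ± 0.11 and JUN by 3.37 ± 0.09. ARC was among the 10 largest fitted rises (8.26 ± 0.75, from 0.43 to 134 CPM). The NF-kB and cytokine list had 10 of 22 members higher and 5 lower (11 and 5 when adjusted over the list alone). The camera test gave an adjusted p = 0.0127, but adjusted p = 0.291 with an estimated correlation and adjusted p = 0.0505 without control replicate 2. CXCL8 rose by 3.25 ± 0.12, IL1A by 1.56 ± 0.08, PTGS2 by 1.39 ± 0.09 and IL6 by 0.84 ± 0.12. NFKBIA, the inhibitor of NF-kB, fell from 71.2 ± 10.7 to 10.7 ± 1.0 CPM (−2.74 ± 0.15) and BIRC3 fell by 1.45.

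Of 20 p53 targets, 6 rose and 3 fell (6 and 3 also when adjusted over the list alone, camera adjusted p = 0.115). BTG2 rose by 3.41 ± 0.12, PLK3 by 1.66 ± 0.11 and GADD45A by 1.21 ± 0.12. CDKN1A, an inhibitor of the cell cycle, went from 46.8 ± 17.4 to 168 ± 86.8 CPM (1.84 ± 0.42, edgeR adjusted p = 0.0176, and adjusted p = 0.0506 without control replicate 3). Apoptosis regulators went both ways, 5 of 29 higher and 8 lower (6 and 8 when adjusted over the list alone, camera adjusted p = 0.54). MCL1 rose by 1.27 ± 0.12, and FADD, an adaptor of death receptors, fell from 99.5 ± 6.4 to 17.9 ± 3.3 CPM. PMAIP1 rose by 1.02 ± 0.22 (edgeR, adjusted p = 0.0148, and 0.055 without control replicate 3). Interferon-stimulated genes had 1 of 20 higher and 6 lower (1 and 6 also when adjusted over the list alone, camera adjusted p = 0.114), with IFIT3 at −1.96 ± 0.18 and IFIT2 at −1.68 ± 0.14.

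Of the 13 mitochondrially encoded protein-coding genes, 12 fell and 1 rose (12 and 1 also when adjusted over the list alone). Their median was −1.07 (camera, adjusted p = 1.86e-10, and adjusted p = 0.0823 with an estimated correlation). MT-CO1 went from 13540 ± 110 to 5668 ± 169 CPM (−1.26 ± 0.04, edgeR adjusted p = 2.86e-06), MT-CO3 changed by −1.39 ± 0.06 and MT-ND5 by −1.29 ± 0.05. The exception, MT-ATP6, rose by 1.80 ± 0.06, but it shares 46 bases with MT-ATP8 on 1 transcript, so their reads cannot be told apart there. MT-ATP8 is 1 of the 12 lower genes (−0.48 ± 0.11). Their summed CPM rose from 4102 to 5555, so the fall of MT-ATP8 does not show a lower transcript. Mitochondrial genes held 5.91% ± 0.05 of the counts in controls and 3.17% ± 0.10 with nanosheets (SD, n = 3). Of 33 nuclear subunits of the respiratory chain, 6 rose and none fell (2 and none when adjusted over the list alone). Camera gave an adjusted p = 0.00317, but adjusted p = 0.488 with an estimated correlation and adjusted p = 0.0839 without control replicate 2. In all, 5 alternatives lost the call and 25 kept it. UQCRB rose by 0.59 ± 0.10 and COX6C by 0.46 ± 0.09.

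**Figure D2:**
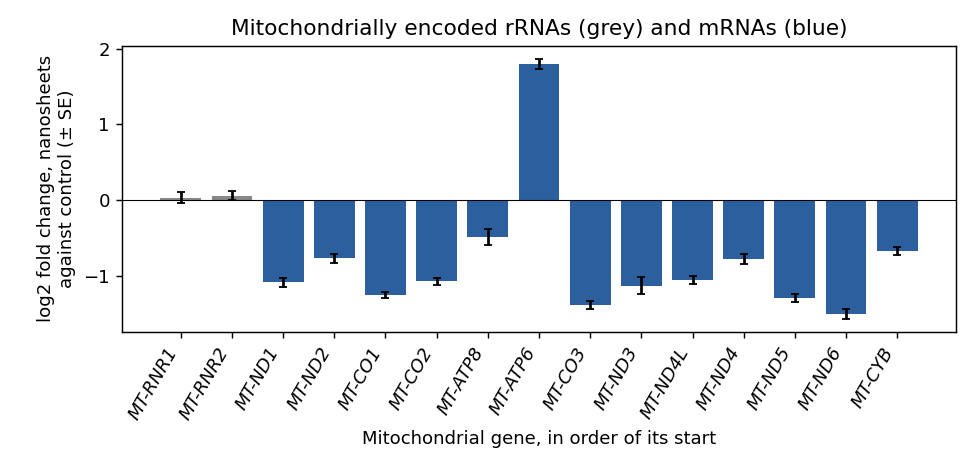
Log2 fold change of each mitochondrially encoded rRNA and mRNA, nanosheets against control, with bars for the SE, in order of start along the mitochondrial genome. MT-RNR1 and MT-RNR2 lie at 0.04 and 0.06, and 12 of 13 protein-coding genes lie below 0.

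Ribosome biogenesis genes fell in 13 of 24 cases and rose in 2 (16 and 2 when adjusted over the list alone). Their median was −0.49 (camera, adjusted p = 7.08e-06, and adjusted p = 0.0464 with an estimated correlation). POLR1B, a core subunit of RNA polymerase I, went from 109.6 ± 7.0 to 34.9 ± 1.2 CPM (−1.65 ± 0.09), POLR1A changed by −1.26 ± 0.08 and NOP2 by −1.02 ± 0.09. Of 39 ribosomal proteins, 10 rose and none fell (11 and none when adjusted over the list alone, median 0.21, camera adjusted p = 0.000162, but adjusted p = 0.476 with an estimated correlation). Of 31 proteasome subunits, 6 rose and none fell (6 also when adjusted over the list alone, median 0.13, camera adjusted p = 0.0127, but adjusted p = 0.467 with an estimated correlation). Both medians turned below 0 with quantile normalization of FPKM, at −0.036 and −0.090. The proteasome call held in 12 of 30 alternatives, was lost in 17 and reversed in 1 (adjusted p from 0.00159 to 0.517). It was lost without control replicate 2 (adjusted p = 0.107) and without nanosheets replicate 2 (0.0576).

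Genes of DNA replication fell in 9 of 27 cases and rose in 1 (11 and 1 when adjusted over the list alone). Their median was −0.26 (camera, adjusted p = 0.000125, and adjusted p = 0.056 with an estimated correlation). CHAF1A changed by −0.93 ± 0.08 and MCM2, part of the replicative helicase, by −0.86 ± 0.10. Mitosis genes fell in 10 of 30 cases (12 lower and 3 higher when adjusted over the list alone). Camera gave an adjusted p = 0.00898, but adjusted p = 0.444 with an estimated correlation and adjusted p = 0.0772 without control replicate 2. PLK1 changed by −1.22 ± 0.13 and CENPA by −1.63 ± 0.23. MKI67, a marker of cycling cells, was at 429 ± 172 and 215.8 ± 17.5 CPM (−0.99 ± 0.25, edgeR adjusted p = 0.0262), a call lost without any 1 of the nanosheet libraries (adjusted p from 0.0668 to 0.0889). Replication-dependent histone genes rose in 9 of 16 cases and fell in none (10 and none when adjusted over the list alone). The median was 1.51 (camera, adjusted p = 1.1e-05, and adjusted p = 0.056 with an estimated correlation). H2BC12 rose by 1.13 ± 0.14 and H2BC21 by 2.37 ± 0.29. These genes are near-identical, and their mature mRNAs mostly lack poly(A) tails, which this library preparation selects.

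Keratinocyte differentiation genes rose in 5 of 18 cases and fell in none (5 also when adjusted over the list alone). Camera gave an adjusted p = 0.0127, but adjusted p = 0.146 with an estimated correlation and adjusted p = 0.113 without control replicate 2. DSC2 rose by 0.99 ± 0.12 and KRT16 by 1.44 ± 0.25. Autophagy and lysosome genes rose in 9 of 30 cases and fell in 1 (10 and 2 when adjusted over the list alone). Camera gave an adjusted p = 0.0127, but adjusted p = 0.123 with an estimated correlation. This list's call was lost in 5 alternatives and kept in 25. MAP1LC3B rose by 0.77 ± 0.08 and SQSTM1 by 0.47 ± 0.06. The other 8 lists were not called by camera. Hypoxia targets had 8 of 20 higher and 5 lower (adjusted p = 0.114; ADM 2.59 ± 0.11), and cholesterol synthesis 7 of 23 higher and 3 lower (adjusted p = 0.104; HMGCS1 1.95 ± 0.11, SQLE −0.52 ± 0.07). Glycolysis had 2 of 17 higher and 1 lower (adjusted p = 0.756). Basal epithelial markers had 5 of 14 higher and 3 lower (adjusted p = 0.406; KRT14 1.31 ± 0.13, TP63 −0.70 ± 0.10). Epithelial-mesenchymal transition genes had 4 of 16 higher and 1 lower (adjusted p = 0.505; SNAI1 4.18 ± 0.15). YAP and TEAD targets had 5 of 14 higher and 5 lower (adjusted p = 0.364; CCN2 4.47 ± 0.11), and actin and adhesion genes 6 of 23 higher and 8 lower (adjusted p = 0.982; MYH9 −0.54 ± 0.05). Endocytosis genes had 4 of 23 higher and 3 lower (adjusted p = 0.511; CAVIN1 0.76 ± 0.07). Adjusted over the list alone, higher and lower members of these 8 lists were 9 and 5, 9 and 3, 2 and 1, 5 and 4, 4 and 3, 5 and 6, 7 and 9, and 4 and 3, in the order given.

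**Figure D3:**
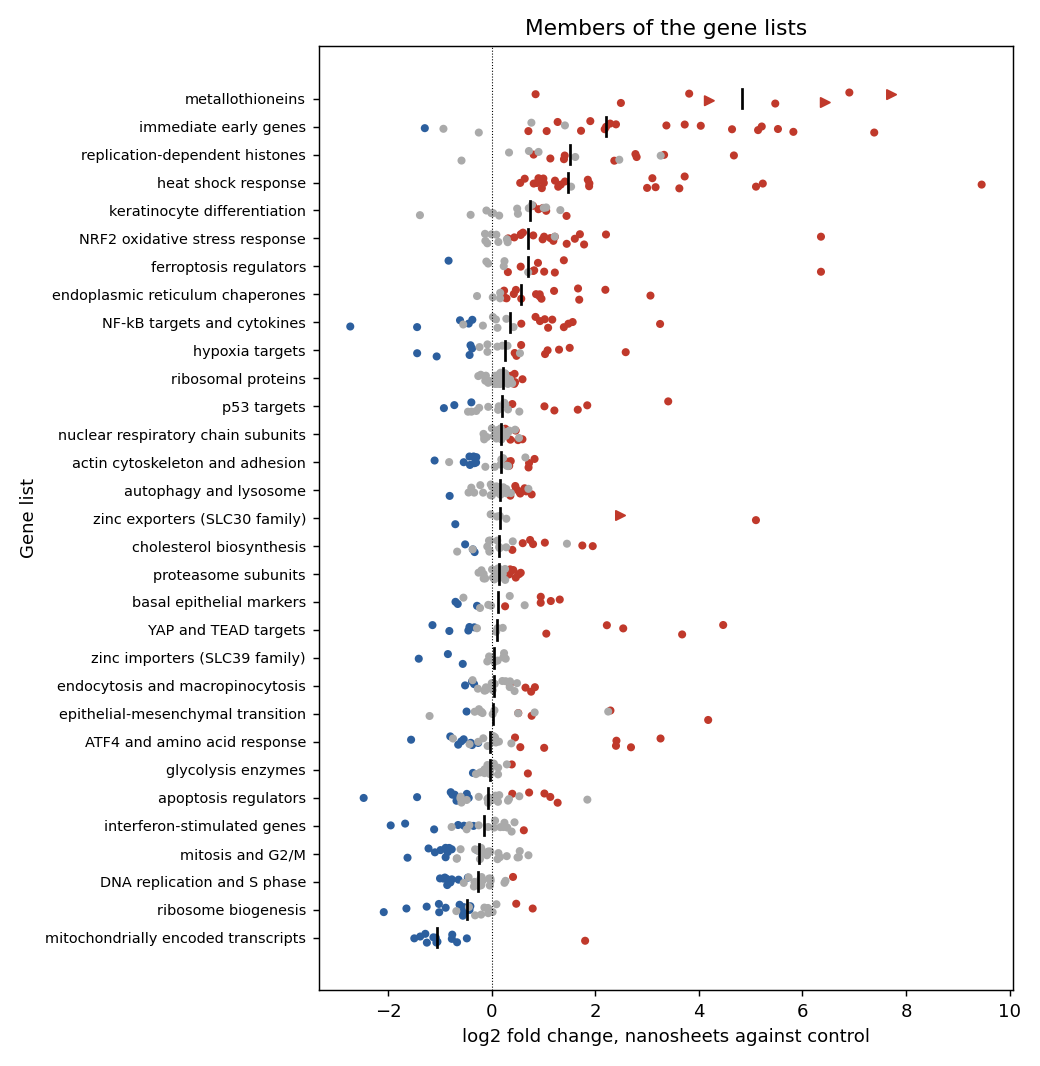
Log2 fold change of every measured member of the 31 lists tested, nanosheets against control, with red for higher, blue for lower and grey for not past the threshold, and a black line at each median. Triangles mark genes at 0 in every control, placed at their lower bound; the metallothionein median lies at 4.83 on this scale and that of the mitochondrially encoded mRNAs at −1.07.

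The lists of fibroblast, endothelial and leukocyte markers had 4, 3 and 4 tested members, too few for a list test. Most of these genes were under 1 FPKM in both groups. Exceptions were CD68 at 12.1 and 13.1 FPKM (edgeR, adjusted p = 0.43), CSF1R at 1.56 and 1.22 FPKM (adjusted p = 0.31) and CDH5 at 4.27 and 1.91 FPKM (adjusted p = 0.00225). COL1A1 rose from 0.35 to 0.63 FPKM (adjusted p = 0.0444), a call lost without each library but control replicate 2 (adjusted p from 0.0602 to 0.141).

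The 10 largest falls among genes with at least 5 FPKM on average were HPS6, MARS2, HASPIN, MTCO1P12, NFKBIA, URB2, INTS5, HJURP, FADD and RIOX1. HPS6 (ENSG00000166189, chromosome 10, 102065349 to 102068036) went from 45.7 ± 7.6 to 3.92 ± 0.56 CPM (−3.55 ± 0.19, edgeR adjusted p = 2.45e-05). MARS2, the mitochondrial methionyl-tRNA synthetase, fell from 43.2 ± 4.8 to 5.52 ± 0.84 CPM and the kinase gene HASPIN from 29.5 ± 1.1 to 4.04 ± 0.59 CPM. URB2 fell by 2.60, INTS5 by 2.53, HJURP by 2.53 and RIOX1 by 2.45 on the log2 scale. MTCO1P12, a nuclear copy of a mitochondrial gene, was at 102.3 ± 116 CPM in controls and 14.2 ± 4.7 CPM with nanosheets (edgeR, adjusted p = 0.0409). Without control replicate 1 its log2 fold change went from −2.85 to −1.33 and its call was lost (adjusted p = 0.0547), as it was without each nanosheet library (0.0972 to 0.132). The call held in 8 of 29 alternatives (adjusted p from 0.0171 to 0.181). The 10 largest rises by fitted log2 fold change, chosen among the same genes, were MT1B, MT1G, HSPA6, HSPA7, ARC, MIR3648-2 and the 4 MIR6724 copies. MIR3648-2, also on chromosome 21, went from 0.011 ± 0.019 to 33.7 ± 2.9 CPM. The MIR6724 genes, between 4.93 and 11.9 CPM with nanosheets, are copies within the ribosomal DNA of chromosome 21, so their reads may belong to any of them. MIR3648-2 and the MIR6724 copies are annotated as miRNA genes, but libraries selected for poly(A) tails do not measure mature miRNAs. Their values thus do not show a rise of miRNAs. Whether carry-over of RNA without poly(A) tails holds part of these rises was not tested. Fitted values of genes at or near 0 in controls depend on the prior count, so this order does not hold for lower bounds: that of MT1G (6.44 on the log2 scale) lies under the rise of MT1M (6.91). The exact permutation test (2-sided) gave its smallest possible p of 0.1 for 24 of the 26 genes named beforehand, and 3 against 3 cannot go lower.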

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

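Counts divided by 4, RLE, upper-quartile and library-total scalings, totals without mitochondrial genes, HSPA1A and HSPA1B, and the robust fit were chosen after seeing the data. An adjusted p under 0.01 left 2129 changed genes (959 higher, 1170 lower), and at least a 2-fold change left 1683 (875 and 808), as stricter thresholds must. With the replicate number as a block, 2720 genes changed (1224 higher, 1496 lower), but the numbers do not pair the samples: deviations of same-numbered libraries correlated at −0.017, −0.009 and 0.014, and 1 of 6 libraries correlated best with its own number. Leaving out each library gave 2786 to 4017 changed genes, 1275 to 2017 higher and 1505 to 2000 lower, with fewer samples in each fit. Without control replicate 3 the counts were 2786, 1281 higher and 1505 lower, and without nanosheets replicate 3 the higher genes were 1275. Limma on FPKM called 2490 genes (970 higher) with a mean of at least 5 FPKM, where 5988 genes were tested, 3533 lower genes with array weights and 1117 higher genes with the replicate block. For the last 2 the cause was not tested. DESeq2 called 5231, and no filter gave 3479. Counts divided by 4 left 14800 genes tested, against 18325 in the main test, and gave 4384 changed (2045 higher, 2339 lower). Some genes thus passed the filter only with undivided counts. The median log2 fold change of all genes was 0.013 with TMM and −0.101 to 0.068 elsewhere, −0.079 with library totals alone. Of the 31 lists tested, 17 were called, 12 to 18 in refits, 5 with an estimated correlation and 26 with fry, which asks another question. Of 14 uncalled lists, 12 were called in some setting, 11 of them with fry. Apart from fry, 4 were called in 1 setting each: zinc exporters without control replicate 3 (higher, adjusted p = 0.038), glycolysis with quantile normalization of FPKM (lower, adjusted p = 0.0176), p53 targets at a mean of at least 5 FPKM (higher, adjusted p = 0.0268) and interferon-stimulated genes with limma on FPKM without a filter (lower, adjusted p = 0.0489). Quantile normalization reversed the medians of ribosomal proteins (−0.036) and proteasome subunits (−0.090) and RPS6 (−0.007), cause not tested. Of 147 called genes named by the rule, 128 were called with their direction in every setting that tested them. Without some library, 15 lost their call: CDKN1A, COL1A1, LDHB, MKI67, MTCO1P12, NDUFA1, NDUFB3, PFKL, PMAIP1, RAB11A, RPS6, SLC30A4, SLC39A13, SLC39A3 and SLC39A9. Medians of 11 uncalled lists and SLC39A10 changed sign in some settings without being called in either. Depth was alike in the 6 libraries.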

Other observations

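The GO and KEGG terms of the deposited table gave 77 called terms of 1677 with camera at the preset correlation (48 higher, 29 lower). With an estimated correlation 0 were called, and the terms are given as directions only. For the gene lists that setting raised p also where the estimate lay under the preset. This 0 therefore does not show an absence of shifts. The smallest adjusted p belonged to higher terms. In cellular zinc ion homeostasis 9 of 20 genes rose and 1 fell (camera, adjusted p = 3.28e-05). In response to unfolded protein 21 of 45 rose and 1 fell (camera, adjusted p = 3.36e-05). Both have an adjusted p of 0.812 with an estimated correlation. The terms that follow are some of the lower ones. Of 112 genes with helicase activity, 39 fell and 5 rose (median −0.34). Camera gave an adjusted p = 0.000463, and adjusted p = 0.812 with an estimated correlation. Of 43 genes of interstrand cross-link repair, which mend covalently joined DNA strands, 17 fell and 1 rose (adjusted p = 0.00143), and of 30 genes of histone H3 acetylation 16 fell and 1 rose (adjusted p = 0.00308). The integrator complex, which processes small nuclear RNAs, had 8 of 15 genes lower and none higher (adjusted p = 0.00877). Of the KEGG term for aminoacyl-tRNA biosynthesis, 12 of 44 genes fell and 1 rose (adjusted p = 0.00548). All 4 terms after helicase activity have an adjusted p of 0.812 with an estimated correlation.

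Tests on the mitochondrial rRNAs and tRNAs, on S phase and on summed histone counts were chosen after the result was seen. So were the sums of MT-ATP6 and MT-ATP8, without and with MTATP6P1, and the tests on snoRNAs. The narrower set of intronless genes and the counts of processed pseudogenes below were chosen then too. The samples make 10 splits into 3 and 3, so no share under 0.1 can be had: the real split gave 4209 changed genes and the highest other 0, and 1 of the 10 splits reached the real count. For called lists the real split gave 17 and the highest other 14, again 1 of 10. Every other split mixes the groups unequally, so part of the group difference stays between its sides and part enters the spread within them. Their counts of genes and lists are therefore not those expected without a treatment effect.

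Of the mitochondrial protein-coding genes, 12 were lower, MT-ATP8 among them. Counts at 20 of 22 mitochondrial tRNA genes tested were lower too, with none higher (median −1.86). Libraries selected for poly(A) tails do not measure mature tRNAs, so these counts do not show a fall of tRNAs. If mitochondrial genomes or mitochondria per cell were fewer, the rRNAs should fall alike. The mean of MT-RNR1 and MT-RNR2 lay 1.11 above the median of the heavy-strand mRNAs. Poly(A) selection leaves an uncertain part of the rRNAs, and carry-over of RNA without poly(A) tails was left open. A fall of the rRNAs could thus be hidden, so this value cannot decide on fewer mitochondria. The highest median of the list was −0.88 over 8 other scalings, and the summed CPM of 11 nuclear copies fell as well (−2.6% of the CPM lost by the mRNAs, with 4 copies lower and none higher), which argues against scaling and against reads moved to nuclear copies. MT-ATP6 and MT-ATP8 summed to 4102 ± 530 and 5555 ± 260 CPM (SD, n = 3, 0.44 on the log2 scale). With the nuclear copy MTATP6P1, which fell from 728.5 to 455.7 CPM, the sums were 4831 ± 532 and 6010 ± 275 CPM (0.32). A rise thus remains in the sums, but it is far smaller than the 1.80 of MT-ATP6 alone. Shifts of reads among these genes may hold much of that rise, and its origin stays open. An effect of the nanosheets on synthesis or decay of mitochondrial mRNAs is another candidate for the fall of the 12 genes, and was not tested.

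Single-exon genes made up 5 of the 10 largest falls. Of all 291 intronless protein-coding genes tested, 28.2% were lower and 16.2% higher, against 15.2% and 11.5% of 13328 genes with introns. The median difference was −0.21, with an interval of −0.42 to 0.01 that includes 0, so a general fall of intronless genes is not established. That set mixes 35 histone genes (median 1.56) and 13 mitochondrial genes. Without both, a narrowing made after this result, 243 genes differed by −0.37 (−0.51 to −0.13), and by −0.30 to −0.44 in decile-matched comparisons. In the full set, matching on GC content left −0.24 and on expression level −0.30, with intervals under 0. Processed pseudogenes lay 0.54 above the intronless genes, where genomic DNA in the controls would lower them alike. But their reads may belong to the genes they copy, so this cannot decide on genomic DNA. Matching on length left −0.19 (−0.33 to 0.10) in the full set, where gene length cannot be told apart, since the interval includes 0 before and after matching. In the narrower set it left −0.30 (−0.41 to −0.07), which argues against length as the whole cause of the fall there. Shorter-lived mRNAs among these genes are a biological candidate that was not tested.

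Replication-dependent histone transcripts rose, while 9 of 27 S phase genes fell and 1 rose, which argues against more cells in S phase. That list had a median of −0.26 (camera, adjusted p = 0.000125, but adjusted p = 0.056 with an estimated correlation). The summed CPM of 63 histone genes went from 79.4 ± 6.7 to 199.8 ± 13.1 (SD, n = 3; 1.33 on the log2 scale), against reads only moving between copies. Other RNAs without poly(A) tails, 12 tested, had a median of 1.83 (0.56 to 4.58), with 6 higher and none lower, RN7SK and RMRP among them, singled out after their values were seen. But 54 snoRNAs, which lack poly(A) tails too, had a median of −1.05 (−1.31 to −0.41), with 6 higher and 8 lower. In controls 48 of the 54 and 10 of the 12 were under 1 CPM. The classes thus disagree at low levels, and carry-over of RNA without poly(A) tails, or new tails on some of it, cannot be told apart from other origins of the rise.

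A hypothesis that transcription runs past gene ends was tested on non-coding genes within 5 kb of expressed genes: the 134 downstream on the same strand had a median 0.14 above 468 other neighbours (−0.16 to 0.37). The interval includes 0, as the criterion against readthrough required, but it also reaches 0.37, so that criterion was too weak to exclude a small effect and the test cannot tell. Processed pseudogenes had 82 of 966 higher and 10 lower (median 0.32), and their reads may in part belong to the genes they copy.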
